A study of Danio rerio with 3 samples.

How the data were processed

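RNA from zebrafish (Danio rerio) scales was measured on 3 Affymetrix Zebrafish Genome arrays, 1 for each of 3 groups, namely control scales, scales kept with 1 nM benzo[c]phenanthrene (BcP) and scales kept with 1 nM 3-hydroxybenzo[c]phenanthrene (3-OHBcP). Per the labels' protocols, the scales were held for 6 h at 15 °C in L-15 culture medium, total RNA was treated with DNase I for 15 min, samples with an RNA integrity number above 8.5 were accepted, and 500 ng of RNA was turned into biotin-labelled cRNA with a kit that primes at the 3' end of transcripts. Whether the control medium held a solvent, and how many fish or scales made up each sample, was not given in the sources used here.

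The authors deposited 1 value per probe set and array, and these values were read as log2 signal from their range, since no header names the scale. The deposited log2 values came from Affymetrix Expression Console per the submitters' processing notes. The software's version, the summarization and normalization algorithm and its background correction were not given in the sources used here. The array medians of 5.32 (control), 5.37 (BcP) and 5.35 (3-OHBcP) on the log2 scale are close together in the deposited values. Of 15502 non-control probe sets, 3497 (22.6%) held exactly the same deposited value on all 3 arrays and 8987 (58.0%) did so on at least 2 arrays. Differences of exactly 0 are therefore common, and a value of 0 is not a precise measure of no change. The deposited values were used with no further scaling, offset or background step.

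Of 15617 probe sets, 115 control probe sets were left out of the gene comparisons and described on their own. The platform annotation gave 1 gene symbol to 10795 of the others, several to 135 and none to 4572, which are unnamed here. Symbols were updated through gene identifiers to a RefSeq gene table of the assembly GRCz12tu, in which 10711 of the 10795 were found. That table served for names alone, so no coordinates are given. The 10795 probe sets stand for 8793 genes, 1539 of which have at least 2 probe sets. Each gene was represented by its probe set with the highest mean over the 3 arrays, and the 5248 genes whose mean was at or above the median of all non-control probe sets (log2 5.35) were kept.

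With 1 array per group no spread between replicates exists, so no test was made and no p-value, standard error or interval is given. The number of arrays limits the precision. For each gene the log2 difference between 2 arrays was taken, and genes at least 2-fold and at least 1.5-fold apart were counted. For each of 33 gene lists the median log2 difference of the kept members was placed among 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A percentile at or below 2.5 or at or above 97.5 is called outside the central range. It describes these 3 arrays, and members of a list that vary together make such percentiles more extreme than those of random genes. Because differences of exactly 0 are common, medians of random lists are often 0. A small list median above 0 can then reach a high percentile, and a list median of exactly 0 ties with many random medians. Lists with fewer than 5 kept members were not placed, which left 31.

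The named genes follow a rule. They are the 10 highest and 10 lowest kept genes for each compound against the control, the 5 highest and 5 lowest for 3-OHBcP against BcP, the 4 kept members farthest in the direction of each list outside the central range, and a set of aryl hydrocarbon receptor, osteoblast, osteoclast and estrogen receptor genes named at any level. The groups, gene lists, comparisons, this rule and the first set of alternatives were fixed before the data were examined. From the set named at any level, cyp1b1, cyp1c2, ahrra, ahrrb, acp5b, tnfrsf11a, tnfsf11, tnfrsf11b, nfatc1, col1a1b and bglap had no probe set under those names in the annotation and were not analysed here.

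Both compounds were set against the same control array, which by itself gives a positive correlation. For comparison, the correlation, covariance and overlap were taken again after shuffling each gene's 3 values among the arrays 1000 times. Shuffling makes the 3 arrays alike and keeps any effect within the spread of values. It therefore shows what a shared array gives among like arrays, and not what no effect would give. The variance of the pairwise differences was split into 1 part per array, and the differences of 2 probe sets of one gene were compared.

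The procedure was tested on simulated data for the 5248 genes in each comparison. Noise was drawn as independent normal values, and only its SD in each of 20 bins of signal level came from the data. The real differences hold many exact ties, and members of a list can vary together. No replicate shows the real noise, so the simulated rates below cannot be set against the counts in the results. Of 100 planted 2-fold genes, 100 came out at least 1.5-fold apart in each of the 3 comparisons. Of 100 planted 1.5-fold genes, 55 passed 1.5-fold in BcP against control, 50 in 3-OHBcP against control and 46 in 3-OHBcP against BcP. Of 5028 unchanged genes, 2, 0 and 5 passed it in the same order. Passing of the 2-fold threshold was not scored. A list of 20 genes shifted by 0.2 reached percentile 100 in each comparison, and 6, 12 and 17 of 200 unchanged lists fell outside the central range in that order. That shift exceeds the median of every real list outside the central range, the largest being 0.17, and smaller shifts were not tried.

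The alternatives fixed then were centring each array on its median, quantile normalization, adding 32 to the linear value, no level filter, a level filter at the 75th percentile, the mean of all probe sets of a gene, leaving out probe sets whose names mark possible matches to several transcripts, and the 1.5-fold threshold. Others, listed with their results in the closing section, were chosen after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.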

Results

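Gene expression was measured in zebrafish scales, thin bony plates of the skin that carry bone-forming osteoblasts and bone-resorbing osteoclasts. After 6 h in culture at 15 °C, 1 array held control scales, 1 held scales kept with BcP, a polycyclic aromatic hydrocarbon, at 1 nM, and 1 held scales kept with 3-OHBcP at 1 nM. The compounds differ by a hydroxyl group at position 3. The study's title poses the question of how such compounds act on the osteoblasts and osteoclasts of scales. There was 1 array per group, so no difference given here has a replicate check, and values describe these 3 arrays. The arrays correlated across probe sets at r = 0.998 in each pairing, and probe sets are not independent replicates.

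Quality probe sets differed somewhat between the arrays. The 18 hybridisation spike-in probe sets, bacterial and phage sequences added in fixed amounts, had a median log2 difference of 0.29 with BcP against the control and 0.082 with 3-OHBcP, while the 24 probe sets for spiked poly-A RNA had medians of 0.022 and 0. The 3' minus 5' log2 difference of the GAPDH control probe sets, a sign of RNA integrity and labelling, was 2.45 on the control array, 2.15 on the BcP array and 2.03 on the 3-OHBcP array. For the actin control probe sets it was -0.47, -0.35 and -0.70 in that order.

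With BcP, most of the genes that stood farthest from the control were lower. The gene irg1l, a homologue of immunoresponsive gene 1, was 2.96-fold lower (log2 signal 6.20 against 7.77), and cyp8b1.3, a relative of the sterol hydroxylase of bile acid synthesis, was 2.42-fold lower. The ubiquitin ligase adaptor gene zyg11 was 2.18-fold lower. The cytochrome P450 gene cyp1a, the classical target of the aryl hydrocarbon receptor that many polycyclic aromatic hydrocarbons induce, was lower at 6.62 against 7.69 (difference -1.07). These were the 4 genes at least 2-fold apart, 2 with 32 added to the linear value, and none of the 5248 was 2-fold higher.

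At 1.5-fold, 31 genes were lower with BcP and 6 were higher, and 99.3% of genes lay within 1.5-fold. That split was 15 lower and 3 higher with 32 added to the linear value, 19 and 2 with the level filter at the 75th percentile, and 47 and 5 with each array centred on its median. It also differed between probe sets marked A and S in their names, which is their orientation. Over all probe sets above the level filter, a count chosen after seeing the data, 36 of 4132 marked A were lower and 3 higher. Of 3619 marked S, 12 were lower and 7 higher. After the 4 genes above, the lowest were rgl1 (log2 difference -0.95), the amino acid transporter gene slc7a7 (-0.92), the tight junction gene cldnf (-0.91), the chaperone gene hsp90aa1.2 (-0.89), cyld2 (-0.78) and fosl1b (-0.78), which encodes a partner of Jun. The highest were runx2a (0.75), a transcription factor of osteoblasts, the carboxypeptidase gene cpa5 (0.72), tcimb (0.72), reln (0.69), rlf (0.64) and ints9 (0.60), followed by thy1 (0.58), alg13 (0.57), sox2 (0.57) and mcoln2 (0.56). The second probe set of hsp90aa1.2 also differed by -0.54, whereas that of rlf differed by 0.

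Osteoblast and bone matrix genes were higher with BcP. Of 21 measured members, 13 were higher, 2 lower and 6 equal, and the list median of 0.078 was at percentile 99.96 of random lists. With each array centred on its median, the list median was 0.032 at an unchanged percentile. Collagen genes stood out, with col1a2 at 0.39, col10a1b at 0.29, col1a1a at 0.28 and col10a1a at 0.19. The secreted matrix genes sparc (0.17) and spp1 (0.15) were also above the control, and the mineralization enzyme gene alpl was close to it (0.02, or -0.02 with each array centred on its median). The master regulator gene sp7 (0.06) and runx2b (0.39) were below the level filter. The probe set named runx2a has the same cluster number and source sequence as a second col1a1a probe set, which differed by 0.53, and the other runx2a probe set differed by 0.15. Whether it measures runx2a or collagen I was not checked here.

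Osteoclast genes showed no common direction with BcP. Of 10 measured members, 4 were higher, 4 lower and 2 equal, with the median at percentile 57.4. The gene for the acid phosphatase of osteoclasts, acp5a, differed by 0.13, the matrix protease genes mmp9 and mmp13a by 0.10 and 0.07, and the bone-degrading cathepsin gene ctsk was at 10.15 on all 3 arrays. The receptor gene csf1ra was below the level filter. Signals that regulate osteoclasts were at percentile 48.9.

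The aryl hydrocarbon receptor list was lower with BcP, with 6 of 8 members lower, a median of -0.17 and percentile 0.43. Besides cyp1a, cyp1c1 (-0.58), the quinone reductase gene nqo1 (-0.35) and the receptor-induced gene tiparp (-0.26) lay below the control, and the receptor gene ahr2 was near it (-0.08). The other 2 probe sets of cyp1c1, both below the level filter, differed by 0 and 0.16 with BcP and by 0 and 0.19 with 3-OHBcP. The list stood at 2.66 with no level filter and, without cyp1a and cyp1c1, a choice made after seeing the data, at 12.3. The cyp1a probe set has the cluster number of the probe sets of mpx, the neutrophil myeloperoxidase gene, and mpx differed by 0.48. The other kept mpx probe set differed by 0.46, and both are of the kind that may match several transcripts.

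Oxidative stress genes were lower with BcP in 16 of 26 members and higher in 8 (median -0.052, percentile 0.37, or 7.5 with the level filter at the 75th percentile). The glutathione synthesis gene gclm (-0.50), the glutathione reductase gene gsr (-0.41), nqo1 (-0.35) and sqstm1 (-0.33) were farthest down. The heat shock list (percentile 1.00) had 15 of 28 members lower, 11 higher and 2 equal. Its farthest members were hsp90aa1.2, hspb8 (-0.66), hsp70.3 (-0.49) and hspa4a (-0.43), and with the level filter at the 75th percentile the list stood at 50.2. It stood at 42.4 with no level filter, 45.8 without probe sets that may match several transcripts and 5.14 with all probe sets of a gene averaged. In the inflammation list 16 of 25 members were lower and 6 higher (percentile 0.22), led by timp2b (-0.54), cxcr4b (-0.48), socs3b (-0.41) and gadd45bb (-0.40). In the p53 and apoptosis list 17 of 30 were lower and 10 higher (percentile 1.23, or 3.38 with no level filter and 3.36 without probe sets that may match several transcripts), among them gadd45ga (-0.41), gadd45bb, mcl1b (-0.33) and xiap (-0.29). The last pair encode inhibitors of apoptosis.

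Epidermal genes were lower in 23 of 45 members and higher in 10 (median -0.028, percentile 0.035), with cldnf, the desmosome gene pkp1b (-0.54), cldna (-0.46) and cldne (-0.40) farthest down. This list stood at 45.4 with the level filter at the 75th percentile, 45.3 with all probe sets of a gene averaged and 2.76 after quantile normalization. The cholesterol list was lower in 10 of 14 members (percentile 1.5), with ggps1 (-0.60), cyp51 (-0.27), acat2 (-0.27) and mylipa (-0.22). It stood at 9.05 when all probe sets of a gene were averaged and 7.57 with no level filter. Oxidative phosphorylation genes were higher in 40 of 67 members (median 0.018, percentile 99.89), such as ndufa13 (0.25), ndufa3 (0.23), ndufb4 (0.18) and ndufa11 (0.18), although centring each array on its median turned that list median to -0.028 at an unchanged percentile. Skeletal muscle genes had 6 kept members, 5 of them higher, with the median at percentile 99.63, including mb (0.28), actc1b (0.25), desma (0.20) and nme2b.2 (0.14). Removing the trend with signal level and probe-set orientation, chosen after seeing the data, put that list at 96.1.

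In all, 10 of 31 lists lay outside the central range with BcP, 3 higher and 7 lower, where 1.55 would do so by chance if genes varied independently. Of these, the aryl hydrocarbon receptor, oxidative stress, heat shock, p53, epidermal, cholesterol and skeletal muscle lists came back inside it under an alternative. Some lists share genes, such as gadd45bb and nqo1, and are not separate counts. The difference of BcP from the control had an SD of 0.156 across genes, and 25.2% of genes were exactly equal.

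**Figure D1:**
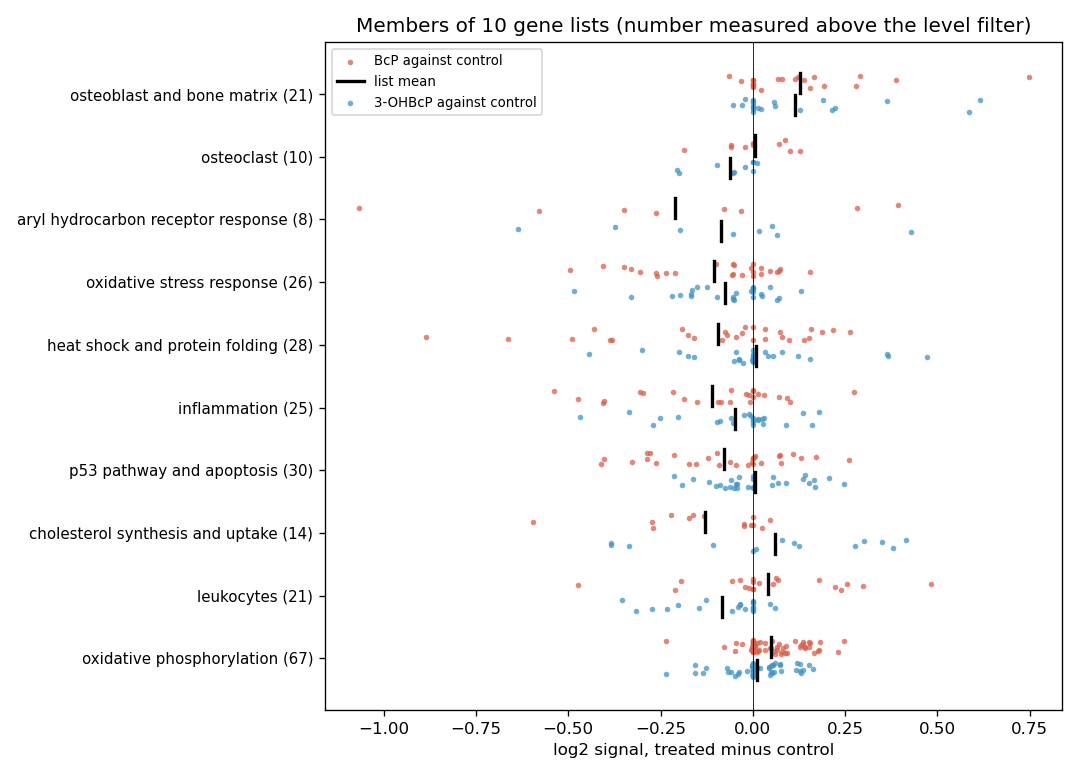
Each point is a kept gene of a list, placed by its log2 signal on the treated array minus that on the control array, with BcP in red and 3-OHBcP in blue, and the black bar is the list mean. The osteoblast list lies mainly to the right of 0 with both compounds (13 and 11 of 21 members higher). The means of the cholesterol list lie on opposite sides, with 10 of 14 members lower with BcP and 9 of 14 higher with 3-OHBcP. Some of its members are lower with both.

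With 3-OHBcP, differences from the control had a smaller SD across genes, and no named gene above the level filter was 2-fold apart, while 1 probe set without a gene name was lower (-1.50). The highest genes were cyp8b1.3 (0.79), tcimb (0.70), cyp8b1.1 (0.66), runx2a (0.62) and the collagen I gene col1a2 (0.59), and these 5 were the genes at least 1.5-fold higher. Below them came efna2a (0.50), bop1 (0.48), ankar (0.48), mcoln2 (0.47) and serpinh1b (0.47), the collagen chaperone gene. Control values of efna2a (5.09), ankar (5.26) and mcoln2 (5.05) were below the level filter, which these genes passed by their mean. The other bop1 probe sets, all below the level filter, differed by 0.14, 0 and 0. The lowest named gene was the transcription factor gene sox4a (-0.89), followed by jac4 (-0.68), the mitochondrial ribosomal protein gene mrpl54 (-0.65), cyp1c1 (-0.64), fosl1b (-0.60) and ntrnl2 (-0.59), which were the 6 genes at least 1.5-fold lower.

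Just short of 1.5-fold were prxl2b (-0.58), rgl1 (-0.57), the sheddase gene adam17a (-0.54) and the cytochrome b5 gene cyb5a (-0.54). The split of 5 higher and 6 lower genes at 1.5-fold was 4 and 8 with each array centred on its median, 5 and 3 after quantile normalization, 2 and 1 with 32 added to the linear value and 4 and 2 with the level filter at the 75th percentile. With all probe sets of a gene averaged, the split was 2 and 6. The SD of the differences was 0.127 across genes, 99.8% of genes lay within 1.5-fold, and 32.6% were exactly equal.

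The osteoblast and bone matrix list was again above the control, with 11 of 21 members higher, 3 lower and 7 equal and the median of 0.013 at percentile 99.90, although centring each array turned that median to -0.015 at an unchanged percentile. Besides col1a2 and runx2a, col1a1a differed by 0.36 and col10a1b by 0.22. The second probe set of col1a1a differed by 0.71, that of col1a2 by 0.32 and that of runx2a by 0.15. Other markers were nearer the control, with sparc at 0.13, alpl at 0.06, spp1 and col10a1a at 0, and, below the level filter, runx2b at 0.35 and sp7 at 0.19. Without col1a1a, col1a2 and runx2a, a choice made after seeing the data, the list stood at percentile 65.5 by its median and 99.6 by its mean.

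Of the 10 osteoclast genes, 6 were lower with 3-OHBcP, 1 was higher and 3 were equal, with the median at percentile 15.3. The values were 0.01 for acp5a, -0.10 for mmp9, -0.05 for mmp13a and 0 for ctsk. Signals that regulate osteoclasts were at percentile 11.3.

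The aryl hydrocarbon receptor list was split evenly with 3-OHBcP, at 4 higher and 4 lower (percentile 25.5), and stood at 97.7 with no level filter. The gene cyp1a differed by -0.37, nqo1 differed by -0.20, tiparp by 0.07 and ahr2 by -0.05. Oxidative stress genes were lower in 15 of 26 members and higher in 7 (median -0.048, percentile 0.88), led by the thioredoxin gene txnb (-0.49), gsr (-0.33), gclc (-0.22) and nqo1. That percentile was 3.69 after quantile normalization, 2.96 with all probe sets of a gene averaged and 2.57 without probe sets that may match several transcripts.

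Cholesterol genes were higher with 3-OHBcP in 9 of 14 members and lower in 4, with a median of 0.096 at percentile 100. The synthesis genes acat2 (0.41), msmo1 (0.38), cyp51 (0.35) and fdft1 (0.30) led them. Skeletal muscle genes had 5 of 6 members higher (percentile 99.05), namely desma (0.26), nme2b.2 (0.14), actc1b (0.13), eno3 (0.08) and a further gene at 0.01, while mb differed by -0.17. This list stood at 93.9 when its mean replaced its median, a statistic chosen after seeing the data, and at 97.1 when all probe sets of a gene were averaged. These 4 lists were the ones outside the central range with 3-OHBcP, where 1.55 would be by chance if genes varied independently.

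Against BcP at the same dose and time, 3-OHBcP gave higher signal for most named genes that stood apart. The gene cyp8b1.3 was 4.17-fold higher (log2 9.04 against 6.98), irg1l 2.46-fold, cyp8b1.1 2.41-fold, hsp90aa1.2 2.38-fold and zyg11 2.30-fold. The carboxypeptidase gene cpa5 was 2.30-fold lower, and these 6 were the genes at least 2-fold apart. Next among the lower genes were mpx (-0.84), the receptor gene notch3 (-0.69), thy1 (-0.65) and sdr16c5b (-0.63). The other kept mpx probe set differed by -0.19, and for 3-OHBcP against control these mpx probe sets had opposite signs (-0.35 and 0.27). At 1.5-fold 25 genes were higher and 7 lower with the hydroxylated compound. Over all probe sets, with or without a gene name, a count chosen after seeing the data, 8 were higher and 5 lower at 2-fold, and 42 higher and 16 lower at 1.5-fold. The 1.5-fold genes numbered 16 with 32 added to the linear value and 21 with the level filter at the 75th percentile, in place of 32. With 1 array for each compound no interval can be put on any of these differences.

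The p53 and apoptosis, immediate early, inflammation and aryl hydrocarbon receptor lists were higher with 3-OHBcP than with BcP. The same BcP array served here and against the control. Against the control, these lists lay inside the central range with 3-OHBcP (14.6, 56.3, 59.8 and 25.5) in the main setting. With BcP, all but the immediate early list (47.5) lay below it (1.23, 0.22 and 0.43). Between the compounds, the oxidative stress, heat shock and endoplasmic reticulum stress lists lay inside the central range (68.4, 63.8 and 64.1). The heat shock median was 0, with 11 members higher, 13 lower and 3 at least 1.5-fold higher. Its mean, chosen after seeing the data, stood at 99.97. In the p53 and apoptosis list 19 of 30 members were higher (median 0.052, percentile 100), with gadd45bb (0.54), gadd45ga (0.31), xiap (0.29) and mcl1b (0.28). In the immediate early list 19 of 35 were higher and 11 lower (percentile 99.97), with klf9 (0.45), ccn2a (0.35), rgs2 (0.34) and dusp1 (0.30). In the inflammation list 14 of 25 were higher and 5 lower (median 0.035, percentile 99.97), with gadd45bb, cxcr4a (0.48), cxcr4b (0.27) and cebpd (0.22). The aryl hydrocarbon receptor list had 6 of 8 members higher (percentile 97.99), with cyp1a at 0.69, tiparp at 0.33, nqo1 at 0.15 and cdkn1bb at 0.05, and cyp1c1 was close to equal (-0.06). Without cyp1a and cyp1c1 that list stood at 94.7, and without probe sets that may match several transcripts at 97.1.

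Cholesterol and matrix genes also stood higher with 3-OHBcP. The cholesterol list had 11 of 14 members higher (median 0.16, percentile 99.99), with acat2 (0.68), cyp51 (0.62), dhcr7 (0.44) and msmo1 (0.41). In the fibroblast and connective tissue list 12 of 21 were higher and 3 lower (median 0.057, percentile 99.99). Its farthest members were serpinh1b (0.63), the collagen crosslinking gene loxl2b (0.30), prrx1a (0.22) and col1a2 (0.20). Osteoblast genes were split, with 7 higher, 9 lower and 5 equal (percentile 63.8), and removing the trend with signal level and probe-set orientation, a step chosen after seeing the data, moved this to 98.8. Osteoclast genes were lower in 6 of 10 members (percentile 5.91), with mmp9 at -0.20, mmp13a at -0.12, acp5a at -0.12 and ctsk at 0. When all probe sets of a gene were averaged, the osteoclast list stood at 0.79.

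**Figure D2:**
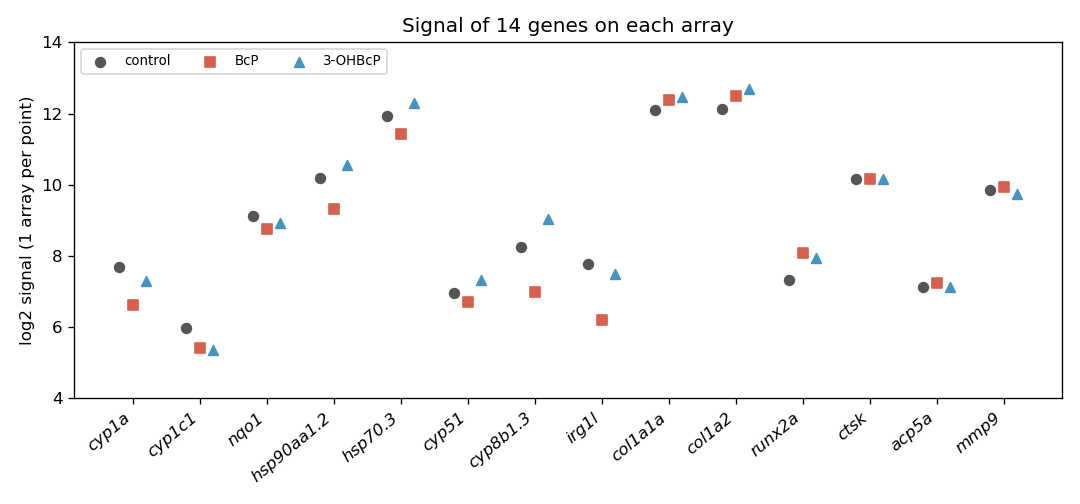
Log2 signal of 14 genes on the control (circles), BcP (squares) and 3-OHBcP (triangles) arrays, with 1 array per point and no error bars because there are no replicates. The cyp8b1.3 signal spans 6.98 with BcP to 9.04 with 3-OHBcP, and ctsk is at 10.15 on each array.

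Both compounds shared some of the genes that stood apart from the control. At 1.5-fold, tcimb and the probe set named runx2a, which may carry collagen I signal, were higher and fosl1b and sox4a lower with both. Independent lists of these sizes would share 0.0057 higher and 0.035 lower genes, and shuffled values, which keep the shared control array, shared 3.97 and 1.65. Across the 5248 genes, which are not independent replicates, the differences of the 2 compounds correlated at r = 0.508, and shuffled values gave 0.501 (0.456 to 0.543). This changed with the filter: r was 0.606 with no level filter, above the shuffled 0.471 to 0.532, and 0.406 with the filter at the 75th percentile, below 0.430 to 0.569. The covariance was 0.0101 beside 0.0104 for shuffled values. Of 3189 genes that differed with both, 74.1% had the same sign, beside 72.9% with shuffled values. The control array could not be split, so part of any shared direction may come from it.

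**Figure D3:**
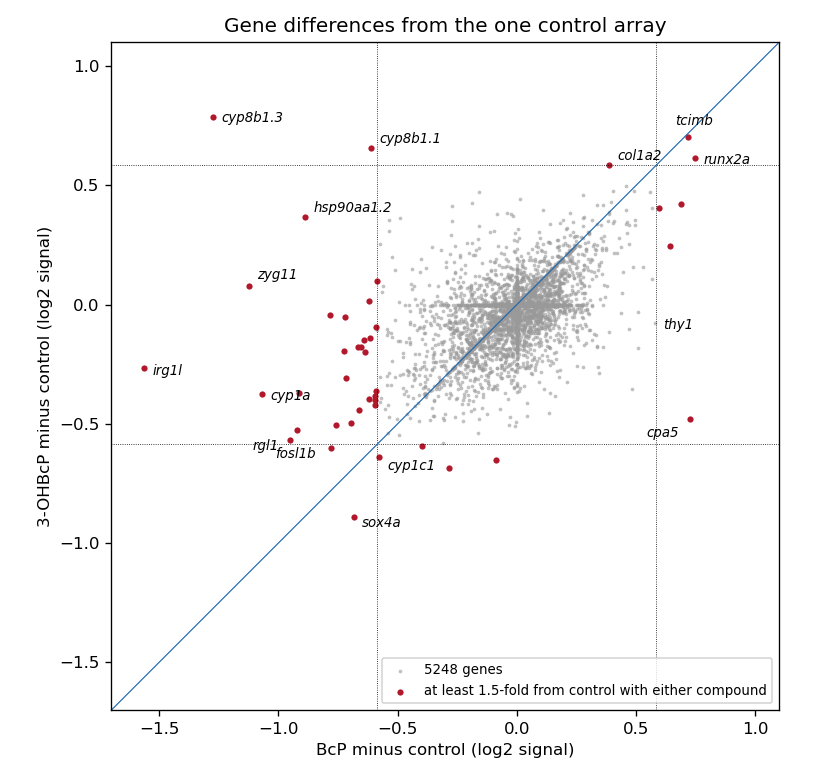
Log2 difference from the control for BcP (horizontal) and 3-OHBcP (vertical) for 5248 genes, with genes at least 1.5-fold from the control with either compound in red, dotted lines at 1.5-fold and the line of equal differences in blue. The genes cyp8b1.3 and cyp8b1.1 lie at the upper left, lower with BcP and higher with 3-OHBcP, and both axes share the 1 control array.

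Of the variance of the pairwise differences, 46.7% went with the BcP array, 33.1% with the control array and 20.2% with the 3-OHBcP array. The control array's part was 42.7% with no level filter and 24.5% with the filter at the 75th percentile. For 638 genes with a second kept probe set, the differences of the 2 probe sets correlated at r = 0.353 for BcP against control, 0.298 for 3-OHBcP against control and 0.528 for 3-OHBcP against BcP, or 0.507, 0.464 and 0.686 with the filter at the 75th percentile. Over all pairs in which both probe sets differed, 61.4%, 60.9% and 74.3% had the same sign in that order. Among genes at least 1.5-fold apart, the second probe set had the same sign in 4 of 6, 2 of 2 and 5 of 5 genes, too few to set against those shares. It was also at least 1.5-fold apart the same way in 1, 0 and 3 of them. Some of these pairs may share probes, which was not checked.

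Of the estrogen receptor genes, esr2a was above the level filter, at a mean log2 signal of 5.76, and differed from the control by 0.36 with BcP and 0.18 with 3-OHBcP, and esr1 (0.27 and 0) and esr2b (-0.14 and 0.05) were below the level filter. The estrogen response list was at percentiles 21.6, 57.8 and 65.8 for BcP against control, 3-OHBcP against control and 3-OHBcP against BcP.

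The other lists lay inside the central range in all 3 comparisons, given here in that same order. Percentiles were 20.01, 31.0 and 65.9 for the vacuolar ATPase, 8.91, 11.2 and 64.0 for the lysosome, 50.7, 66.3 and 66.9 for conjugation and xenobiotic transport, and 49.6, 62.0 and 64.1 for endoplasmic reticulum stress. They were 49.3, 56.8 and 57.0 for the cell cycle, 50.7, 10.7 and 14.7 for matrix proteases, 50.5, 59.7 and 59.6 for scale development signalling, and 51.3, 4.28 and 64.8 for calcium and vitamin D handling. Red blood cell genes were at 72.6, 73.6 and 15.1, leukocyte genes at 50.9, 4.23 and 18.8, and nerve and glia genes at 96.4, 85.4 and 20.5. The circadian clock was at 49.0, 58.1 and 60.1, hypoxia and glycolysis at 55.0, 69.3 and 31.4, and fatty acid metabolism at 51.5, 67.5 and 96.8. Cytosolic ribosome genes were at 95.1, 50.03 and 4.28 and proteasome genes at 96.1, 66.2 and 9.60. Osteoclast-regulating signals in the comparison of the compounds were at 95.6. Pigment cell and vascular endothelium genes had 4 and 2 kept members and were not placed.

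In the comparisons not described with them above, the lists were as follows. Heat shock genes were at 58.7 for 3-OHBcP against control and 63.8 for 3-OHBcP against BcP, inflammation at 59.8 for 3-OHBcP against control, and p53 and apoptosis at 14.6 there. Epidermal genes were at 52.1 and 58.2, oxidative phosphorylation at 58.5 and 8.28, and the fibroblast list at 48.3 for BcP and 58.1 for 3-OHBcP against control. Immediate early genes were at 47.5 and 56.3 against control, and oxidative stress and skeletal muscle at 68.4 and 82.3 between the compounds.

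By the list mean, a statistic chosen after seeing the data, 10 placements that were inside the central range by the median lay outside it. For 3-OHBcP against control these were epidermis (0.04, list mean -0.056), matrix proteases (0.93), leukocytes (1.62), oxidative phosphorylation (99.44) and the fibroblast list (99.99, list mean 0.081). Between the compounds they were heat shock (99.97, list mean 0.10), leukocytes (0), oxidative phosphorylation (1.19) and the proteasome (2.15), and for BcP against control immediate early genes (1.88).

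Among probe sets with no gene name or several, 5 were at least 2-fold apart in a comparison. One that names several hsp90 genes differed from the control by -0.95 with BcP and 0.41 with 3-OHBcP, and was 1.36 higher with 3-OHBcP than with BcP. The other 4 were lower with 3-OHBcP than with BcP, the farthest by -2.49 and each at least 2-fold.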

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

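The tests of single probe-set noise, single samples, mpx signal, collagen I transcripts, tissue mix, RNA integrity and the control array were chosen after the result was seen, as were the removal of the trend with level and orientation, the matching on orientation, the lists without named genes, the use of list means and the count over all probe sets.

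The median of the cholesterol list and a pair of genes stood on opposite sides of the control with the 2 compounds. Members of the list did not all do so. With BcP and 3-OHBcP in that order, acat2 (-0.27 and 0.41) and cyp51 (-0.27 and 0.35) did. However, ggps1 (-0.60 and -0.38) and mylipa (-0.22 and -0.39) were lower with both. The genes msmo1 and fdft1, higher with 3-OHBcP, were near the control with BcP (-0.02 and -0.01). Other kept cyp51 probe sets differed by -0.37 and 0.79, and by 0.16 and 0.39. The list's median log2 difference was -0.078 with BcP and 0.096 with 3-OHBcP, but the BcP side came back inside the central range with no level filter (percentile 7.57, median -0.024) and with all probe sets of a gene averaged (9.05, -0.024). For cyp8b1.1 the differences were -0.61 and 0.66, and for cyp8b1.3 they were -1.27 and 0.79. The 2 genes are near relatives whose probe sets have the same cluster number, so they are not separate evidence. The difference was not tested, because each compound has 1 array.

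Outside the gene comparisons, a probe set with no gene name here differed from the control by 1.00 with BcP and -1.50 with 3-OHBcP. The hybridisation spike-in probe sets, which hold no scale RNA, stood above the control by a median of 0.29 with BcP and 0.082 with 3-OHBcP. Neither difference was tested.

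More named genes stood higher than lower with 3-OHBcP against BcP, 25 against 7 at 1.5-fold, and over all probe sets 42 against 16, or 8 against 5 at 2-fold. After quantile normalization, which removes differences in overall brightness, 24 were higher and 6 lower. After removing the mean difference of each signal level and probe-set orientation, 24 were higher and 5 lower. Shifts of the mean therefore do not account for the pattern, but they were small to begin with (-0.00049 and -0.019 for probe sets marked A and S in their names). A wider spread in a single orientation class would not be removed by either step. Over all probe sets, those marked A were 27 higher and 6 lower, and those marked S 15 and 10, so a part of probe-set class stays open. Noise of single probe sets stays open, because 2 genes had a second kept probe set from another sequence cluster, and it had the same sign in 2. These were hsp90aa1.2 and dsc2l, the latter named after its values were seen. A difference between single scale samples cannot be told apart from an effect of the hydroxyl group, since arrays per group number 1.

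The gene cyp1a was lower with BcP than in the control, the opposite of the induction for which it is known. Signal from mpx, which has the same cluster number, would move cyp1a the way mpx moved, but the kept mpx probe sets were higher by 0.46 and 0.48. With the trend removed cyp1a still differed by -1.05. Lower activity of the aryl hydrocarbon receptor is a hypothesis that stays open, since the list without cyp1a and cyp1c1 was at percentile 12.3 by its median and 56.4 by its mean. A difference between single samples, unrelated to BcP, was not testable either.

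The osteoblast list was higher than the control with both compounds, and with random lists matched on level and orientation it stayed at percentiles 99.92 and 99.90 (the 3-OHBcP median was -0.015 with each array centred), which argues against that trend as the whole cause. The list was also placed without col1a1a, col1a2 and runx2a, the last because its probe set may carry collagen I signal, which was not checked. For BcP it was then at 99.03 by its median and 99.1 by its mean, so collagen I transcripts alone do not account for that part. For 3-OHBcP the values were 65.5 and 99.6, so the point stays open there. Another mix of tissue stays open. Skeletal muscle, with 6 kept members, was also higher with both compounds (99.63 and 99.05), and epidermis was lower with BcP (0.035). With 3-OHBcP, epidermis was at 52.1 by its median and 0.04 by its mean. By the median, the lowest of 6 tissue lists other than epidermis and osteoblast was inside the central range, at 48.3 with BcP and 4.23 with 3-OHBcP. RNA integrity or labelling stays open too, since the 3' minus 5' difference of GAPDH differed from that of the control array by -0.30 with BcP and -0.43 with 3-OHBcP, while that of actin differed by 0.12 and -0.23. An effect of both compounds cannot be told apart from a deviation of the control array, of which there was 1.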

How the results depend on the processing

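The choices added after seeing the data were counting all probe sets, removing the trend with level and orientation, the mean in place of the list median, random lists matched on orientation, and lists without named genes. Of 352 values under an alternative for the results that answer a comparison, 300 stayed within the tolerance, 25 came back inside the central range, 3 moved outside it and 24 moved by more than the tolerance. Centring adds a constant to each array, so under it list percentiles, the correlation, the variance parts and the second probe sets could not change. Those values count among the unchanged by construction, here and for the other lists below. The tolerance was the same side of the percentile bounds for a list, a factor of 1.5 for a count, the same side of the shuffled range for the correlation of the compounds, the central range of resampled genes or gene pairs for the variance and for second probe sets, and 1 SD of the differences of genes of like level for a named gene. It does not count signs of list medians or the split of a count, and with centring the median turned from 0.013 to -0.015 for the osteoblast list with 3-OHBcP and from 0.018 to -0.028 for oxidative phosphorylation with BcP. The counts below are in the order BcP against control, 3-OHBcP against control, 3-OHBcP against BcP. At 1.5-fold in place of 2-fold, 37, 11 and 32 genes stood apart in place of 4, 0 and 6, and 4 in place of 0 did so the same way with both compounds. These 1.5-fold counts were 18, 3 and 16 with 32 added, 21, 6 and 21 with the filter at the 75th percentile, which tests fewer genes, and 58, 23 and 58 over all probe sets, which counts more features. At 2-fold, 2 genes remained for BcP with 32 added, and all probe sets gave 1 and 13 for the other comparisons. The split at 1.5-fold for BcP, 6 higher and 31 lower, was 5 and 47 with centring, and that for 3-OHBcP, 5 and 6, was 4 and 8 with centring and 5 and 3 with quantile normalization. With all probe sets of a gene averaged, the 3-OHBcP split was 2 and 6. Over all probe sets, the 2-fold split between the compounds was 8 higher and 5 lower in place of 5 and 1. The correlation of the compounds was 0.606 with no filter (shuffled 0.471 to 0.532) and 0.406 with the filter at the 75th percentile (0.430 to 0.569). The control array's part of the variance was 42.7% with no filter and 24.5% with the filter at the 75th percentile, in place of 33.1%. Second probe sets correlated with the first at 0.507, 0.464 and 0.686 with that filter, and at 0.344 between the compounds with no filter. With quantile normalization, oxidative stress with 3-OHBcP was at percentile 3.69 and epidermis with BcP at 2.76. With no filter, the BcP lists of aryl hydrocarbon receptor, heat shock, p53 and cholesterol genes were at 2.66, 42.4, 3.38 and 7.57, and the receptor list with 3-OHBcP moved out to 97.7. With the filter at the 75th percentile, oxidative stress, heat shock and epidermis with BcP were at 7.50, 50.2 and 45.4. With all probe sets of a gene averaged, heat shock, epidermis and cholesterol with BcP were at 5.14, 45.3 and 9.05, oxidative stress and skeletal muscle with 3-OHBcP at 2.96 and 97.1, and osteoclast genes between the compounds moved out to 0.79. Without probe sets that may match several transcripts, heat shock and p53 with BcP were at 45.8 and 3.36, oxidative stress with 3-OHBcP at 2.57 and the receptor list between the compounds at 97.1. Removing the trend put skeletal muscle with BcP at 96.1 and osteoblast genes between the compounds at 98.8, and the mean put skeletal muscle with 3-OHBcP at 93.9. Without col1a1a, col1a2 and runx2a the osteoblast list with 3-OHBcP was at 65.5. Without cyp1a and cyp1c1 the receptor list was at 12.3 with BcP and 94.7 between the compounds, or 56.4 and 88.2 by the mean. Beyond the choices that set the genes counted, the cause was not tested. For lists inside the central range, 23 values moved outside it and 644 did not. Of the named genes' differences, 88 moved by more than the tolerance and 1682 did not. Signal near background limits genes under the filter and may limit those just above it, and many small differences are exact ties in the deposited values. No paired analysis was possible because each group has 1 array.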

Other observations

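All values in this part were picked after the data were seen. The 3 genes named next were picked because they stood lower with BcP and higher with 3-OHBcP than in the control. The glucocorticoid-responsive chaperone partner gene fkbp5 differed by -0.54 and 0.36, or 0.89 between the compounds. The vitamin D hydroxylase gene cyp24a1 differed by -0.57 and 0.25, or 0.83 between the compounds. The gene klf9, another glucocorticoid target, differed by -0.19 and 0.26. The fixed list of calcium and vitamin D handling lay inside the central range at 51.3, 4.28 and 64.8 for BcP against control, 3-OHBcP against control and 3-OHBcP against BcP, and no statement about hormone pathways is made.

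The leukocyte list lay inside the central range by its median, at 18.8 between the compounds and 4.23 for 3-OHBcP against control, but at 0 and 1.62 by its mean. Between the compounds, 11 of 21 measured members were lower with 3-OHBcP than with BcP, 3 were higher and 7 equal, and the list mean was -0.12 while its median was -0.0073. Besides mpx, the members farthest down were srgn (-0.45), coro1a (-0.40), runx3 (-0.33) and ptprc (-0.30), all named after their values were seen. The mpx probe set in the list differed by -0.84, while the other kept mpx probe set differed by -0.19.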
